A study of Brassica rapa with 12 samples.

How the data were processed

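Messenger RNA was measured by sequencing in 12 leaf libraries of Brassica rapa, a rapid-cycling stock, in 4 groups of 3. The groups are Flg22 (the bacterial flagellin peptide flg22 at 10 uM), Psm (the leaf pathogen Pseudomonas syringae pv. maculicola at an OD600 of 0.01), and a separate mock group for each, Mock_F and Mock_P, which received 10 mM MgCl2 alone. Per the labels' protocols, plants were 15 days old, a pair of leaves on each plant was infiltrated by syringe, each leaf was frozen in its own tube at 9 hours, and libraries were made with a TruSeq RNA kit and sequenced on a MiSeq. The labels do not say which libraries came from which plants, so p-values measure the spread between these libraries, which may in part be leaves of the same plant.

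Reads were trimmed with Trimmomatic 0.32 and aligned with TopHat2 2.0.10, per the submitters' processing notes. The values the authors deposited per locus and library are estimated counts of fragments assigned to each locus from the aligned reads, which need not be whole: 1.12% of the values above 0 were not whole within 1e-06. They also deposited FPKM values per locus and library, scaled for locus length and library size, and a group FPKM per locus, which equalled the mean of the 3 libraries of the group within 0.0001 of its size for 100% of the values. Per the file headers, the layout is that of Cuffdiff. Its version, the genome build and the use of strand are not given in the sources used here. Fragments from overlapping loci on opposite strands, and fragments split between near-identical gene copies, can therefore not be told apart, which bears on any locus with a close paralog in this genome. Replicates are numbered from 0 in the deposited values and from 1 in the labels; number 0 was taken as replicate 1, and so on. Coordinates are those of the deposited loci, counted from 1.

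The deposited values covered 43324 loci, of which 30977 had at least 1 fragment in the 12 libraries. Most loci carry only a Brassica identifier of the form Bra followed by digits. Of 41004 such identifiers, 1 matched a symbol in the RefSeq gene table of the assembly CAAS_Brap_v3.01, and that gene had 0 fragments. The planned gene lists and cell type markers could therefore not be matched and were not tested, and loci are named here by identifier only. A further 727 loci, called unannotated here, carry no gene name and are given by their identifier beginning XLOC. They held 1.96% of all fragments and were kept in the tests. Whether they overlap annotated genes was not examined. Another 218 loci merge several annotated genes.

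Estimated counts were rounded to whole numbers and analysed with edgeR 4.0.16 in R 4.3.3 (filterByExpr by group with its default minimum count of 10, TMM normalization, quasi-likelihood test, Benjamini-Hochberg adjustment, adjusted p under 0.05). All 12 libraries were fitted with 1 mean per group, which leaves 8 residual degrees of freedom. A total of 16062 loci were tested. TMM factors ranged from 0.884 to 1.15, and the common biological coefficient of variation was 0.295. The 4 comparisons were Flg22 against Mock_F, Psm against Mock_P, Mock_F against Mock_P, and the difference of the first pair of responses, (Psm minus Mock_P) minus (Flg22 minus Mock_F). The flg22 and Psm comparisons share no control library. Levels are given as CPM, counts scaled by library size and TMM factor, and standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic. Library pairs of each group were compared by a chi-square test over loci with at least 20 fragments in the pair. No pair was identical, and every pair differed by more than sampling noise (chi-square per locus from 1.82 to 11.4), so no library was counted as a copy of another. Leaves of one plant would also differ by more than sampling noise, so this does not show that the libraries come from separate plants.

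Loci named by identifier follow a planned rule: adjusted p under 0.05, a mean of at least 10 fragments per library in the higher group, no overlap between the libraries of the groups compared (this clause was not applied to the difference of responses), and then the largest fitted changes, at most 2 upward and 2 downward per comparison where no gene name exists. Where all libraries of a group had 0 fragments, the fold is a lower bound against a floor of 3 fragments over that group's libraries together. Per library, 3 fragments correspond to between 2.66 and 4.99 CPM. Where it had 1 to 3 fragments, a ratio of fragment shares is given with its exact 95% binomial interval. Floors and intervals cover counting error only.

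The test was run on simulated counts for the same 16062 loci with 200 loci changed per comparison. Of 4-fold changes, it recovered 52% for the flg22 comparison, 59% for Psm, 49% for the mock comparison and 9% for the difference of responses. Of 2-fold changes, it recovered 3%, 3%, 4% and 0%, in the same order. Loci called without a simulated change were 1 of 56, 3 of 65, 1 of 54 and 2 of 11 calls. The adjustment is stricter when few loci change, and the real flg22 and Psm tests called 5819 and 7175 loci. These recovery rates therefore do not carry over to those 2 tests. Of the loci called there, 88.4% and 87.6% had a fitted change of at least 2-fold. The difference of responses combines 4 group means, and its median SE was 0.544, against 0.388 for flg22.

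The comparisons, the rule for named loci, the gene lists and the following alternatives were chosen before the data were examined. The alternatives were size factors and the Wald test of DESeq2 1.42.0, no filter on low counts, a filter on a mean of 20 fragments per library, fits of only the libraries compared, a replicate block, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), a 2-fold threshold, and leaving out each library in turn. After the data were seen, 3 were added: leaving out unannotated loci, leaving out ribosomal RNA loci, and summing replicates 1 and 2 of each group into 1 unit, which gives 8 units, 2 per group. Clustering of called loci along chromosomes was tested by shuffling the calls within chromosomes 10000 times. Other calculations used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3.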

Results

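Leaf messenger RNA was sequenced from 4 groups of 3 libraries, Flg22, Psm and a mock group for each, 9 hours after infiltration. The 12 libraries were shallow, with between 601278 and 1128095 estimated fragments each. The Flg22 libraries held 763111, 709285 and 787339 fragments, and the Mock_F libraries 713373, 904595 and 601278. The Mock_P libraries held 628018, 879318 and 1058598 fragments, and the Psm libraries 832983, 1044912 and 1128095. Between 22861 and 25064 loci had at least 1 fragment in a library. The groups differed little in the mean number of detected loci, from 23888 ± 219 (SD, n = 3) in Flg22 to 24282 ± 809 (SD, n = 3) in Psm.

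Elicited and mock-infiltrated leaves separated along the first principal component of log2 CPM, which held 58.4% of the variance. The second component, with 13.3%, separated Flg22 from Psm libraries, while on it the mock libraries of both experiments lay together. On the third component, with 6%, Mock_F replicates 1 and 2 lay at -47.85 and -49.35 and Mock_P replicates 1 and 2 at 34.81 and 41.66. Replicate 3 lay at 3.63 in Mock_F and 2.11 in Mock_P. Correlations of log2 CPM across loci, which are not independent replicates, had medians of 0.874 within Flg22, 0.861 within Mock_F, 0.898 within Mock_P and 0.887 within Psm. Between the mock groups the median was 0.859. It was 0.556 between Flg22 and Mock_F and 0.510 between Psm and Mock_P.

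**Figure D1:**
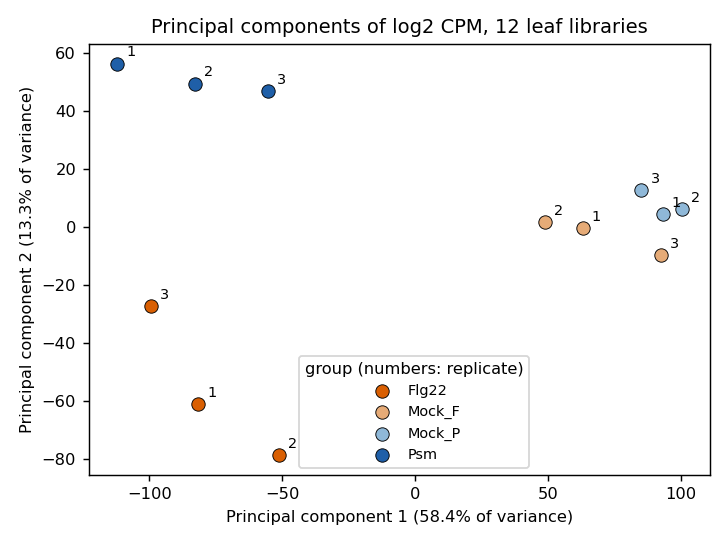
Principal components 1 and 2 of log2 CPM for the 12 libraries, coloured by group, with the replicate number beside each point. All 6 mock libraries lie at 48.9 or above on component 1 and all 6 elicited libraries at -51.4 or below; component 2 runs from -27.3 and below in Flg22 to 46.7 and above in Psm.

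The libraries of a group were not equally alike. Loci with 0 fragments in one library and at least 20 in the other numbered between 0 and 2 for replicates 1 and 2 of a group, in all 4 groups. For pairs that included replicate 3 of the same group, they numbered between 44 and 79. Between same-numbered libraries of the 2 mock groups the median was 52 loci, and between mock libraries of different number it was 46.5.

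**Figure D2:**
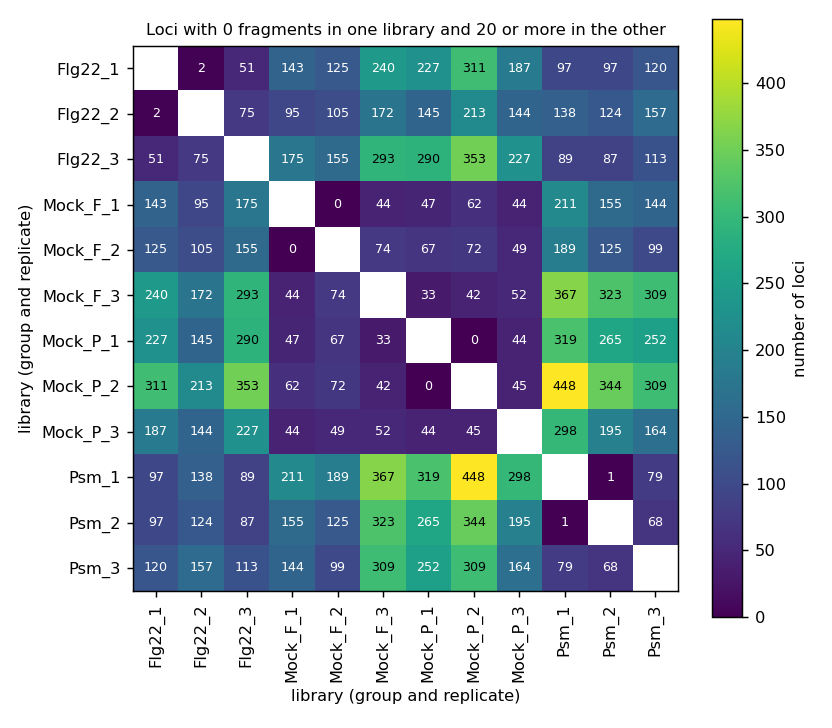
Number of loci with 0 fragments in one library and 20 or more in the other, for every pair of the 12 libraries (both axes: group and replicate; colour and printed value: number of loci). Within each group, replicates 1 and 2 differ at 2 loci or fewer and either of them differs from replicate 3 at 44 loci or more.

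The first comparison asked which leaf transcripts change 9 hours after infiltration of flg22, a peptide of bacterial flagellin that plants perceive through the receptor kinase FLS2. The leaf transcriptome changed broadly: 2774 loci rose and 3045 fell, together 36.2% of the 16062 tested (edgeR quasi-likelihood test, adjusted p under 0.05). The median size of the change among called loci was 1.77 on the log2 scale. Changes of 8-fold or more were found for 487 loci that rose and 358 that fell, with loci at 0 in one group counted at their lower bound. Most of the loci most abundant in mock-infiltrated leaves fell. They were chosen for a high level in mock leaves, so any broad change would tend to lower their share. Loci most abundant in elicited leaves were not examined. Of the 100 loci most abundant in the other experiment's mock libraries, 87 fell and 2 rose, while 3045 of all 16062 tested loci fell. The share of all fragments held by these 100 was 17.1% ± 3.36 (SD, n = 3) in Mock_F and 4.79% ± 0.101 (SD, n = 3) in Flg22. Among the 500 most abundant, 327 fell and 29 rose. At the other end of the range, 62 loci without a fragment in Mock_F rose, to a median of 18.5 CPM.

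The locus Bra003448 on chromosome A07 (13246761 to 13255098) had 189.8 ± 188 CPM (SD, n = 3) in Flg22 and no fragment in Mock_F, at least 140-fold higher, with an adjusted p of 0.00175 by edgeR. Its 3 Flg22 libraries held 119, 20 and 306 fragments. Bra030917 on chromosome A08 (768318 to 770069) rose at least 76.6-fold, to 103.5 ± 66.6 CPM (SD, n = 3), with an edgeR adjusted p of 0.000144. Both loci also rose with Psm. The largest falls were in unannotated loci. XLOC_038628 on chromosome A09 (11694649 to 11695458) had 145.8 ± 73.2 CPM (SD, n = 3) in Mock_F and 0 fragments in Flg22, at least 110-fold lower (edgeR adjusted p = 0.000143), but it also had 0 fragments in all Mock_P and Psm libraries. With the DESeq2 test this call was lost (adjusted p = 0.098, with 5.07e-11 to 0.098 over all alternatives). XLOC_003472 on chromosome A01 (15669041 to 15670383) had 48.2 ± 9.11 CPM (SD, n = 3) in Mock_F and 0 fragments in Flg22, at least 36.3-fold lower (edgeR adjusted p = 0.00134). The filter on a mean of 20 fragments per library removed XLOC_003472 before the test. With replicates 1 and 2 of each group summed, 3928 loci were called for flg22.

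The second comparison asked the same of the living pathogen, Pseudomonas syringae pv. maculicola, against its own mock. More loci passed the test: 3538 rose and 3637 fell, together 44.7% of those tested, with a median change of 1.78 on the log2 scale among called loci (edgeR quasi-likelihood test, adjusted p under 0.05). Changes of 8-fold or more were found for 859 loci that rose and 468 that fell, counted in the same way. The abundant mock transcripts fell here too. Of the 100 loci most abundant in Mock_F, 84 fell and 1 rose, while 3637 of all 16062 tested loci fell. The share of fragments held by these 100 was 18.4% ± 1.08 (SD, n = 3) in Mock_P and 7.36% ± 1.5 (SD, n = 3) in Psm. Of the 500 most abundant, 306 fell and 38 rose. A further 92 loci without a fragment in Mock_P rose, to a median of 29.1 CPM. The 2 experiments were not compared at equal depth. Mean fragments were 1001997 in Psm and 855311 in Mock_P, against 753245 in Flg22 and 739749 in Mock_F, so the larger counts for Psm may in part reflect depth.

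Bra013138 on chromosome A03 (20249916 to 20253781) rose at least 244-fold, from 0 fragments in Mock_P to 285.3 ± 65.6 CPM (SD, n = 3) in Psm (edgeR adjusted p = 0.000861). It also rose with flg22 (edgeR adjusted p = 0.00628). Flg22 replicates 1, 2 and 3 held 36, 2 and 139 fragments, and Mock_F 0. Bra003448, named above for flg22, rose at least 174-fold, to 203.9 ± 129 CPM (SD, n = 3), with an edgeR adjusted p of 0.00111. Bra029124 on chromosome A03 (6474066 to 6475481) had 34.2 ± 17.6 CPM (SD, n = 3) in Mock_P and 0 fragments in Psm, at least 34.3-fold lower (edgeR adjusted p = 0.00668). In the other experiment it had 0, 0 and 15 fragments in Mock_F replicates 1, 2 and 3 and 0 in all Flg22 libraries, so it was also silent in some mock leaves. The Psm call for Bra029124 was lost with the DESeq2 test (adjusted p = 0.133, with 1.29e-05 to 0.133 over the alternatives that tested it). The filter on a mean of 20 fragments per library removed this locus before the test. Bra006567 on chromosome A03 (4080233 to 4080868) fell from 221.3 ± 120 CPM to 1.04 ± 0.182 CPM (SD, n = 3), with an edgeR adjusted p of 0.000285. It had 552 fragments in Mock_P and 3 in Psm, a ratio of 215.6 (exact 95% interval 73.4 to 1048). With flg22 it fell too, with a log2 change of -3.85 (edgeR adjusted p = 0.00701). Neither Bra013138 nor Bra006567 had a called difference of responses. With a filter on a mean of 20 fragments per library, 4781 loci were called for Psm, of 9267 tested. With replicates 1 and 2 of each group summed, 4916 were called.

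**Figure D3:**
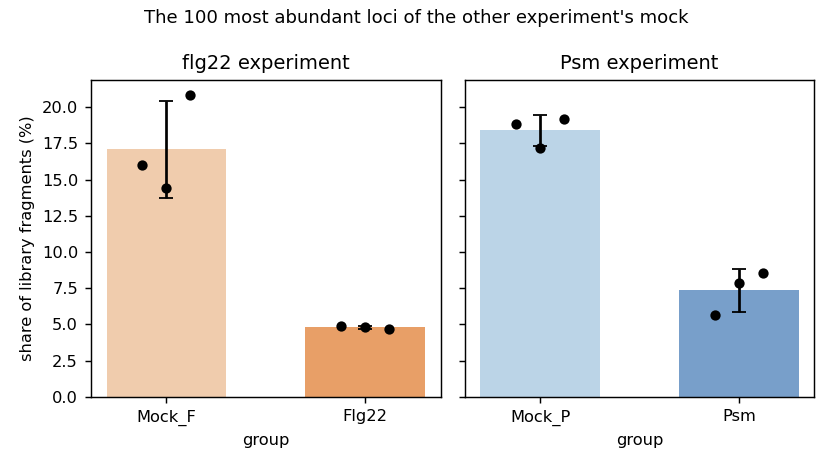
Share of each library's fragments (percent) held by the 100 loci most abundant in the other experiment's mock libraries, for the flg22 experiment (left) and the Psm experiment (right). Bars are means of 3 libraries, error bars are SD and points are libraries; the lowest mock library is at 14.4% and the highest elicited library at 8.56%.

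The libraries of the compared groups did not overlap in these shares in either experiment. With 3 libraries against 3, an exact permutation test cannot give a two-sided p below 0.1, the value that both comparisons of shares reach.

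Both elicitors changed many of the same loci in the same direction. A total of 1921 loci rose with both, where independent lists of these sizes would share 611.0, and 2271 fell with both, where independent lists would share 689.5. These were 69.3% of the loci that rose with flg22 and 74.6% of those that fell, and 54.3% and 62.4% of those that rose and fell with Psm. Across the 16062 tested loci, which are not independent replicates, the log2 fold changes correlated with a Pearson r of 0.723 and a Spearman rho of 0.725. Loci called in opposite directions numbered 68, of which 17 rose with flg22 and fell with Psm and 51 did the reverse. With replicates 1 and 2 of each group summed, 1141 loci rose with both and 1516 fell with both.

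Being called with 1 elicitor only rarely came with a called difference. Of 1559 loci called with flg22 and not with Psm, 90 had a difference of responses past the threshold, and 80.3% had the same sign with Psm. Of 2915 called with Psm and not with flg22, 195 had such a difference, and 80.4% had the same sign with flg22. These shares were 5.77% and 6.69%, against 2.52% of all tested loci. The test of the difference is less precise, with a median SE of 0.544 against 0.388 for flg22. The lack of a called difference therefore does not show that the responses were equal.

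**Figure D4:**
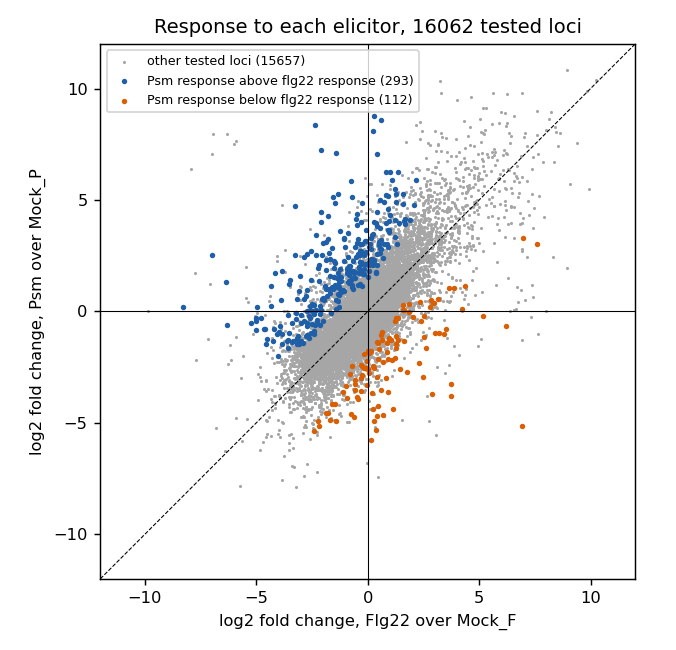
Log2 fold change of Psm over Mock_P (vertical) against that of Flg22 over Mock_F (horizontal) for 16062 tested loci, one point per locus, with the line of equal response dashed. Coloured points are the 405 loci whose responses differed, 293 with the Psm response above the flg22 response and 112 below; Pearson r over all points is 0.723.

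The difference between the responses was tested directly, each elicitor against its own mock. It passed the threshold for 405 loci, 293 with the Psm response above that to flg22 and 112 below (edgeR quasi-likelihood test, adjusted p under 0.05). In the first set, 141 loci rose with Psm without a call for flg22, 64 fell with flg22 without a call for Psm, 47 fell with flg22 and rose with Psm, 26 fell with both and 15 rose with both. In the second set, 54 fell with Psm without a call for flg22, 26 rose with flg22 without a call for Psm, 17 rose with flg22 and fell with Psm, 11 fell with both and 4 rose with both. The test adds the Mock_F minus Mock_P shift to the Psm minus Flg22 one, and the median mock shift had the sign of the difference in each pattern. In the order given, it was 1.08, 0.28, 0.85, 0.01 and 1.44 in the first set and -0.73, -0.39, -1.66, -0.92 and -0.67 in the second, on the log2 scale. When Psm and Flg22 libraries were compared without the mocks, 334 of the 405, which were chosen on the same libraries, were called in the same direction.

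The largest differences were in unannotated loci. XLOC_017810 on chromosome A04 (16641792 to 16642677) had 51.2 ± 20.7 CPM (SD, n = 3) in Psm, 0 fragments in Mock_P, 1 fragment in the Flg22 libraries together and 6 in Mock_F (edgeR adjusted p = 0.0172). XLOC_014870 on chromosome A03 (2375109 to 2376313) had 74.6 ± 7.95 CPM in Mock_F, 0.428 ± 0.742 in Flg22, 9.61 ± 16.6 in Mock_P and 64.1 ± 15.6 in Psm (SD, n = 3; edgeR adjusted p = 0.00908). Its Mock_P fragments all lay in replicate 3. In the opposite direction, XLOC_004370 on chromosome A01 (3289675 to 3290305) had 18.3 ± 8.66 CPM (SD, n = 3) in Flg22, 1, 0 and 12 fragments in Mock_P replicates 1, 2 and 3 and 0 in Mock_F and in Psm (edgeR adjusted p = 0.0377). XLOC_043312 on Scaffold010737 (1 to 228) had 8.06 ± 7.74 CPM in Flg22, 0.479 ± 0.83 in Mock_F, 21.4 ± 14 in Mock_P and 1.19 ± 2.06 in Psm (SD, n = 3; edgeR adjusted p = 0.0436), so that the mock groups differed more at this locus than Flg22 and Psm did. With replicates 1 and 2 of each group summed, edgeR called 0 of 18649 tested loci for the difference, with 1784 at an unadjusted p under 0.05. If no locus differed, a share of about 0.05 of the tested loci would pass that threshold by chance. No other tool was run on the summed units, and none of these 4 named loci kept its call in that setting. XLOC_014870 lost its call in that setting alone, and XLOC_017810 also without Mock_F replicate 1 or 2. XLOC_004370 lost it without Mock_P replicate 3, which held most of its Mock_P fragments (edgeR adjusted p = 0.166, with 0.000365 to 0.22 over all alternatives), with a replicate block and without most other single libraries, and XLOC_043312 with these and with each limma setting. The stricter filter removed XLOC_017810, XLOC_004370 and XLOC_043312 before the test. Leaving out 1 library moved the count from 405 to 111, 252 and 780 without Flg22 replicates 1, 2 and 3, to 101 and 120 without Mock_F replicates 1 and 2, to 129 and 182 without Mock_P replicates 1 and 2, and to 253 and 215 without Psm replicates 1 and 2.

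The mock groups received the same solution, so their comparison measures how far the libraries of the 2 experiments differed without an elicitor. It cannot separate a difference between experiments from one between the plants or libraries that make up each group. The mock groups differed at 55 loci, 29 higher in Mock_F and 26 higher in Mock_P (edgeR quasi-likelihood test, adjusted p under 0.05). These were 0.342% of those tested. Unannotated loci made up 14.5% of the 55 and 2.70% of all tested loci. Among loci higher in Mock_F, 6 of the 433 tested unannotated loci were called against 0.147% of the rest (Fisher's exact test, p = 0.000104, adjusted p = 0.000832 over 8 tests). Among loci higher in Mock_P, 2 of the 433 were called, or 0.462% against 0.154% of the rest (Fisher's exact test, p = 0.155, adjusted p = 0.412). The largest differences were again in such loci. XLOC_038628, described above, had fragments in the 3 Mock_F libraries alone, and XLOC_008826 on chromosome A02 (16626937 to 16628224) had 63.2 ± 43.8 CPM (SD, n = 3) in Mock_F and 0 fragments in Mock_P, at least 54-fold higher (edgeR adjusted p = 0.0453). XLOC_038613 on chromosome A09 (3571722 to 3572499) had 0 fragments in Mock_F and 26.6 ± 9.26 CPM (SD, n = 3) in Mock_P, at least 19.7-fold lower (edgeR adjusted p = 0.0164). XLOC_029703 on chromosome A08 (3330586 to 3332378) was at least 12.2-fold lower in Mock_F (edgeR adjusted p = 0.0374). Not all 4 loci followed the experiment in the elicited libraries. XLOC_008826 had 26, 24 and 16 fragments in Psm replicates 1, 2 and 3, although Mock_P had 0. XLOC_029703 had 5, 9 and 12 fragments in the Flg22 replicates, although Mock_F had 0. XLOC_038613 did follow it, with 0 fragments in Flg22 and 26, 30 and 52 in Psm. The 4 calls were not stable. XLOC_038628 lost its call with the DESeq2 test (adjusted p = 0.527, with 1.2e-09 to 0.527 over all alternatives) and without Mock_F replicate 1 or Mock_P replicate 2. XLOC_008826 lost it with the stricter filter, with each limma setting, and without Mock_F replicate 1 or 2 or any 1 Mock_P library (edgeR adjusted p from 2.31e-05 to 0.636 over all alternatives). XLOC_038613 and XLOC_029703 lost it with a replicate block and without replicate 1 or 2 of either mock group, and XLOC_029703 also without Mock_P replicate 3. The stricter filter removed these 2 loci before the test, and the filter on only the libraries compared removed XLOC_008826 and XLOC_029703. With replicates 1 and 2 of each group summed, 1 locus was called, which was none of these 4, and leaving out 1 library gave 3, 3 and 94 loci without Mock_F replicates 1, 2 and 3, and 5, 2 and 36 without Mock_P replicates 1, 2 and 3.

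Loci that rose lay next to each other more often than shuffled calls did. With flg22, 547 neighbouring, non-overlapping pairs of tested loci both rose, against 455.2 ± 17.6 (SD over 10000 shuffles within chromosomes; permutation p = 1e-04, the smallest these shuffles can give). With Psm there were 877 such pairs against 749.6 ± 21.7 (permutation p = 1e-04, again the smallest possible). Pairs that both fell numbered 574 with flg22 against 554.2 ± 19.1 (permutation p = 0.156) and 811 with Psm against 783.9 ± 21.8 (permutation p = 0.111). With overlapping neighbours included, which can share fragments, the pairs that fell numbered 610 with flg22 against 565.3 ± 19.3 (permutation p = 0.0114) and 845 with Psm against 799.7 ± 21.8 (permutation p = 0.0217), so the result for falling loci depends on those pairs. The calls of the difference of responses showed 6 upward pairs against 5.26 ± 2.24 (permutation p = 0.439). No chromosome held more called loci than the rest after adjustment over 22 tests per comparison. Whether neighbouring loci are copies of one another was not analysed here.

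Runs of at least 4 neighbouring tested loci that all rose numbered 24 with flg22 and 53 with Psm, and runs that all fell 19 and 37. The number of runs was not compared with shuffled calls. The runs below were picked after their values were seen, as the longest and the most changed. On chromosome A01 from 5170071 to 5207165, 6 loci rose with both elicitors. Their summed level was 290.7 ± 28.1 CPM in Flg22, 108.6 ± 8.81 in Mock_F, 290.3 ± 57.1 in Psm and 81.6 ± 15.1 in Mock_P (SD, n = 3). On chromosome A05 from 10934367 to 11088056, 5 loci rose with flg22, from 42.4 ± 14.5 to 928.7 ± 184 CPM (SD, n = 3), with a median log2 change of 4.55. Of these, 3 rose with Psm, and the sum was 17.3 ± 5.57 CPM in Mock_P and 236.2 ± 79.4 CPM in Psm (SD, n = 3). None of the 5 had a called difference of responses. On chromosome A07 from 18910077 to 18978848, 8 loci in a row rose with Psm, from 339.9 ± 38.5 to 1121 ± 148 CPM (SD, n = 3), and 2 of them with flg22. On chromosome A09 from 17482033 to 17595520, 4 loci rose with both elicitors, from a sum of 66.5 ± 28.3 CPM in Mock_F to 276.9 ± 127 in Flg22, and from 59.2 ± 12.6 CPM in Mock_P to 269.5 ± 81.8 in Psm (SD, n = 3).

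**Figure D5:**
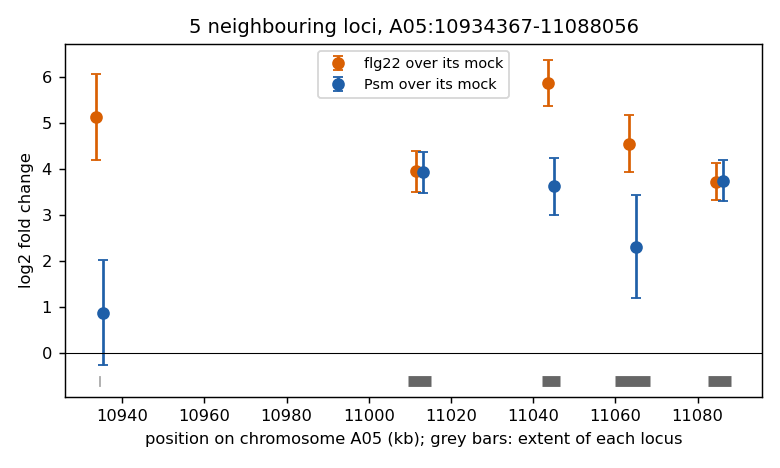
Log2 fold change (points) with its SE (bars) of 5 neighbouring loci on chromosome A05, by position in kb, for flg22 (orange) and Psm (blue) over their own mocks; points are shifted sideways slightly and grey bars show the extent of each locus. All 5 rose with flg22, by a median of 4.55, and 3 rose with Psm.

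Fragments from ribosomal RNA, which are a small residue in libraries meant for messenger RNA, were fewer in Psm than in Mock_P. All 8 tested 28S rRNA loci were called lower, with a median log2 change of -4.65 (edgeR quasi-likelihood test), and none of the 8 was called with flg22, where the median was 0.40. These 8 loci carry the same annotation, and fragments split between near-identical copies cannot be told apart, so they are not 8 independent results. With DESeq2 size factors the medians were -4.61 and 0.43. For Psm, limma called 6 of the 8 lower with a median of -2.45 on the log2(FPKM + 1) scale, 5 of 8 there without a filter, and 6 of 8 with a median of -3.65 on the log2(FPKM + 0.1) scale. The longest run of loci that fell with Psm, on chromosome A06 from 20104801 to 20197551, consisted of 6 rRNA loci. Ribosomal RNA made up 0.00686% ± 0.00138 of fragments in Psm and 0.137% ± 0.198 in Mock_P (SD, n = 3). The Mock_P value was spread over 0.366%, 0.0210% and 0.0241% in replicates 1, 2 and 3. The shares in Flg22 and Mock_F were 0.0948% ± 0.0139 and 0.0601% ± 0.0319 (SD, n = 3). Without Mock_P replicate 1, 6 of the 8 loci were called lower and the median was -2.89.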

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

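The counts of other splits of the libraries, the exchange of replicate 3 between Flg22 and Psm and the summing of replicates were chosen or run after the result concerned was seen; the comparison without the mocks and the correlation across experiments were fixed before their values were known.

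The responses to the 2 elicitors differed at 405 loci by a test of the difference itself. Of the 6 libraries of each simpler comparison, 10 splits into 3 and 3 exist, too few for a share under 0.05. The real flg22 split gave 5819 loci and the highest other split 0, and the real Psm split gave 7175 and the highest other 0. The real mock split gave 55 and the highest other 19. In each of these cases 1 of the 10 splits, the real one, gave as many. For the difference, 2 of 100 drawn splits gave at least 405 loci, the real one included. The other one, with 578, kept all Flg22 and Psm libraries in place and exchanged replicate 3 of the mock groups. Among the 91 drawn splits that moved a Flg22 or Psm library, the highest count was 7. With Flg22 and Psm kept and the mock groups exchanged whole, 831 loci were called. Splits that leave the Flg22 and Psm libraries in place keep the contrast between them, which called 1562 loci without the mocks. Of the 9 drawn splits of that kind, the real one had the second highest count. The splits therefore bear on the contrast of Psm with Flg22 libraries and do not exclude chance for the difference of responses.

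The mock libraries stay open as what sets part of this difference: 82.5% of the 405 loci were called in the same direction between Psm and Flg22 libraries, but they were chosen on those libraries, so a high share was built in. Of the 55 loci that differed between the mocks, 16 are among the 405, and without Mock_F or Mock_P replicate 1 or 2 the count was 101 to 182. It was 111 and 252 without Flg22 replicates 1 and 2 and 253 and 215 without Psm replicates 1 and 2, so a drop is not particular to the mocks. Without replicate 3 it was 607 for Mock_F, 316 for Mock_P, 780 for Flg22 and 350 for Psm. If replicates 1 and 2 of a group are leaves of one plant, only 2 arrangements of the Flg22 and Psm libraries keep them together, which is too few to exclude chance; exchanging replicate 3 gave at most 25 loci, and the summed units gave 0. A batch of plants or of infiltration that shifts both groups of an experiment alike is subtracted with the own mock, but one that changes the response itself cannot be told apart from the elicitor, because each experiment used 1 elicitor: across loci, the Mock_F minus Mock_P and Flg22 minus Psm differences correlated with an r of 0.076. A biological difference between a peptide and a living bacterium remains possible and is untested beyond this.

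Loci called in opposite directions by the 2 elicitors with a called difference numbered 64, with a median Mock_F minus Mock_P shift of -1.66 for the 17 with the Psm response below and 0.85 for the 47 with it above; with replicates 1 and 2 of each group summed, edgeR called 0 loci for the difference. Of the 8 tested 28S rRNA loci, 5 had a called difference of responses, with the Psm response below that to flg22; with replicates 1 and 2 of each group summed, 0 of 8 had one by edgeR, and across the alternatives between 0 and 7 had one. The number was 1 without Flg22 replicate 1, without Mock_F replicate 1 or 2 and without any 1 Psm library, and 2 without Flg22 replicate 2 or Mock_P replicate 1.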

How the results depend on the processing

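Summing replicates 1 and 2, and leaving out unannotated or ribosomal RNA loci, were chosen after seeing the data. Counts for flg22 stayed within 1.5 times the reported 5819 under each alternative run, with 4550 to 6036 when 1 library was left out. Those for Psm did so too, with 5824 to 7244, except that a mean of 20 fragments per library gave 4781 of 9267 loci tested. The share of tested loci called varied too. For flg22, 4226 of 9267 were called with that filter, and 5229 of 30977 with limma on log2(FPKM + 1) without a filter. Of the 5819 reported calls, these settings kept 70.5% and 74.1%, and the summed units kept 65.0%. The 55 loci that differed between the mocks became 166 with the DESeq2 test, 283 with no filter on low counts, 131 with only the libraries compared, and 2 to 94 without 1 library. The 405 differing responses became 665 with the DESeq2 test, 998 with no filter, 206 with limma on log2(FPKM + 1), 145 on log2(FPKM + 0.1), 184 on log2(FPKM + 1) without a filter, and 101 to 780 without 1 library. With replicates 1 and 2 of each group summed, the mock count was 1 and that of differing responses 0 by edgeR. These came from 8 units in place of 12. Of 18649 loci tested there, 1009 and 1784 had an unadjusted p under 0.05, where a share of about 0.05 would by chance alone. For the other changed counts the cause was not tested. A replicate block gave 5469 loci for flg22, 6872 for Psm, 31 for the mocks and 285 for the difference; the numbers do not pair libraries across groups, since deviations of same-numbered libraries correlated between -0.175 and 0.148 and not every library correlated best with its own number. The correlation of the responses was 0.615 on log2(FPKM + 1) in place of 0.723. For loci named by identifier, 230 of 289 values under alternatives kept their call, 59 lost it and 0 reversed. Tests of gene lists were not run, for want of matched names, nor was a fit of only the libraries compared for the difference, which uses all groups. Simulated at this depth, spread and number of libraries, with 200 loci changed, 3% of 2-fold changes were recovered for flg22 and 0% for the difference. These rates do not carry over to the real flg22 and Psm tests, which called many more loci and so had a less strict adjustment. Whether depth, spread, number of libraries or number of changed loci sets the limit was not tested.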

Other observations

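The test at 10 to 19 fragments was fixed before its result was seen; the tests of depth, of a shared replicate number and of ribosomal RNA were chosen after the pattern was seen, as were the regions below.

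Some runs of neighbouring loci fell with flg22 and, in their summed level, fell less with Psm. They were picked as the longest or most changed runs for flg22, so a smaller change with Psm is partly built in. On chromosome A05 from 5412314 to 5427095, 4 loci fell with flg22, from a sum of 1002 ± 479 CPM in Mock_F to 53.6 ± 3.33 in Flg22, with a median log2 change of -4.35. With Psm, 1 of them fell, and the sum was 1586 ± 329 CPM in Mock_P and 779.9 ± 94.8 in Psm (SD, n = 3). For 3 of the 4 the difference of responses was called, though 1 pair of these loci overlaps and can share fragments. On chromosome A08 from 15619056 to 15677286, 5 loci fell with flg22, from 1940 ± 212 to 374.9 ± 30.8 CPM (SD, n = 3), while with Psm 2 fell and 1 rose. Their sum was 1612 ± 359 CPM in Mock_P and 1152 ± 335 in Psm (SD, n = 3). Only 1 of the 5 had a called difference, and the locus from 15619056 to 15619861 fell alike with both, by -2.81 with flg22 and -2.85 with Psm on the log2 scale.

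The response of each library was scored as the mean log2 level of loci that rose in the other experiment minus that of loci that fell there, relative to the own mock. Scores were 2.58, 2.04 and 2.94 in the Flg22 libraries and 3.64, 3.1 and 2.59 in the Psm libraries. The Mock_F libraries lay between -0.479 and 0.379, and the Mock_P libraries between -0.0551 and 0.0305. The SD was 0.452 in Flg22 and 0.438 in Mock_F, and 0.526 in Psm and 0.0478 in Mock_P (n = 3 each); these spreads were not tested against each other.

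Loci that merge several annotated genes fell with flg22 more often than the rest: 42 of 144, or 29.2%, against 18.9% (Fisher's exact test, p = 0.00267, adjusted p = 0.0214 over 8 tests). With Psm the shares were 27.8% and 22.6% (Fisher's exact test, adjusted p = 0.214). Neither test matched loci for level or length, and loci abundant in mock leaves fell more often than the rest. The higher share is therefore not shown to come from merging itself.

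Replicates 1 and 2 of each group shared which loci were silent, and replicate 3 differed from them, in all 4 groups. The values argue against depth, since sampling alone would give at most 0.00484 such loci in a pair with replicate 3, where 44 to 79 were seen. Same-numbered libraries of the 2 mock groups differed at a median of 52 loci, and those of different number at 46.5. A batch shared by libraries of one replicate number across both experiments would therefore not account for the pattern by itself. Such a batch within an experiment, or beside another cause, was not tested. A candidate explanation is that replicates 1 and 2 are 2 leaves of one plant and replicate 3 a leaf of a different plant; a batch that joins replicates 1 and 2 within each group stays open too, and the tables do not separate them. The pattern also held at 10 to 19 fragments against 0 in 4 of 4 groups, but in the same libraries, so this favours neither. If 2 plants are behind each group, the summed counts (3928 for flg22, 4916 for Psm, 1 for the mocks and 0 for the difference) may be the closer ones.

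Unannotated loci were over-represented among those silent in one library of a group and at 20 or more fragments in another: 17.6% of the 410 with that depth, against 1.33% of annotated loci (Fisher's exact test, p = 1.01e-51). They also led the largest differences between the mock groups and between the responses, where all 8 named loci are of this kind.

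The lower ribosomal RNA level in Psm than in Mock_P rests in part on 1 library. Without Mock_P replicate 1, 6 of the 8 28S loci were still called lower, but these loci are not independent of each other. The ribosomal RNA share in Mock_P replicates 2 and 3, 0.0210% and 0.0241%, was still above the highest share in a Psm library, 0.00768%. How the libraries were prepared stays open as an explanation, since the share differed 17.4-fold between Mock_P libraries that received the same solution, and the labels give no preparation batch. A biological effect of the bacterium on ribosomal RNA was not tested separately and cannot be told apart from preparation here.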
